A study of Rattus norvegicus with 10 samples.

How the data were processed

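RNA from pancreatic islets of rats aged 40 days was measured on 10 Affymetrix expression arrays, 2 for each of 5 groups. Per the labels, DR+/+ and JB are diabetes-inducible animals without the mutation at the lyp locus, JBlyp/lyp animals are diabetes prone and homozygous for it, and F344 and F344lyp animals are healthy controls. The growth protocol has DR+/+ and JBlyp/lyp descend from DRlyp/+ parents, while the treatment protocol names DRlyp/lyp and WF rats and neither JB group. How JB relates to DR is not stated, so that JB and JBlyp/lyp share 1 background is read from their names. The protocols describe islet isolation from fasted male animals (the sex was not settled from the arrays) by collagenase digestion and a density gradient, RNA extraction with TRIzol, and biotin-labelled cRNA.

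The deposited values are 1 log2 intensity per probe set and array, made by the submitters with GCOS and RMA, per the submitters' processing notes. The versions of GCOS and RMA are not given in the sources used here. The values fit a log2 scale, with array medians between 5.39 and 5.44. Of 31099 probe sets, 57 Affymetrix controls were set aside and 31042 were tested. No raw scans were analysed here, so probe-level steps were taken as the submitters made them. For arrays, the number of arrays limits the precision, and 2 per group is the smallest number that gives a spread. The labels call the arrays biological replicates but do not say whether each came from a separate animal or from pooled islets, so the p-values measure the spread between these samples.

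A linear model with 1 mean per group was fitted to each probe set with limma 3.58.1 in R 4.3.3, and the 8 comparisons were taken as contrasts of the 5 group means, with moderated two-sided tests (eBayes). Residual degrees of freedom were 5, to which the prior added 4.72. The comparison of BB with F344 sets the mean of the DR+/+, JB and JBlyp/lyp group means against the mean of the F344 and F344lyp group means, and spread between groups of 1 side does not enter its error. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum and no filter on dim probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

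Gene symbols came from the annotation of the array. It gives 1 symbol for 20826 probe sets, several for 436 and none for 9780 of those tested. The 20826 cover 14217 genes, of which 4525 have more than 1 probe set, and a gene is represented by its probe set with the highest mean over the 10 arrays. Identifiers of 20764 of these probe sets were found in the RefSeq table of assembly GRCr8, 0 symbols were changed through it, and 68 had no match. That table served only for names and for which genes neighbour each other.

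The comparisons, the tests, the alternatives, the 25 gene lists and the rule for naming genes were fixed before the data were examined. The rule named, among called genes whose compared arrays do not overlap, the 12 largest rises and 12 largest falls for BB against F344, and 6 of each for the other comparisons (the 6 largest of either sign for the difference between the lyp effects). It also named up to 4 called members of each list with the largest difference, the Gimap genes and the islet hormone genes Ins1, Ins2, Gcg, Sst and Ppy, and passed over uncharacterised loci. A gene that the rule names for BB against F344 is not reported here. The lists hold antioxidant, glutathione transferase, endoplasmic reticulum stress, oxidative phosphorylation, interferon response, antigen presentation, chemokine and inflammation, immediate early and stress, hypoxia and glycolysis, cell cycle, apoptosis, regenerating and Gimap genes, and markers of beta, other endocrine, acinar, ductal, T, B, macrophage and dendritic, mast and eosinophil, endothelial, stellate and fibroblast, erythroid, and nerve and Schwann cells. A further list of sex-linked genes served as a check of the labels. After the data were seen, 2 marker lists, for mesothelium and intestinal epithelium, were added. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation and with fry. With the estimated correlation 0 of the 25 fixed lists passed in each of the 8 comparisons. With the preset correlation 14 passed for BB against F344, and fry, which does not compare a list with other genes, called 18.

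The model was tested on simulated data built from the spread of these arrays, in 5 runs with 200 of 31042 probe sets changed by known amounts. For BB against F344 the recovered shares were 43.6% at a log2 change of 0.5, 98% at 1 and 100% at 2. For lyp in JB they were 3.2%, 70.8% and 99.6% at the same sizes, and for lyp in F344 4.8%, 72.4% and 100%. False calls made up 7.17% of calls for BB against F344, 7.07% for lyp in JB and 5.97% for lyp in F344. A list shifted by 0.5 was found in 5 of 5 runs and an unshifted one in 0. Probe sets were simulated as independent and without spread between groups of 1 side. The runs therefore do not show how camera does with correlated list members.

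Alternatives tried were a filter on dim probe sets, equal array medians, quantile normalization, a trend in the prior variance, array weights, 1 probe set per gene, a replicate block, a fold minimum of 1.5, leaving out each array, and leaving out each BB group. Models with only the groups compared, with 2 group means, and with the strain as a random block were also fitted. An alternative added after the data were seen takes the log2 difference of the 3′ and 5′ Gapdh control probe sets of each array, a sign of RNA and labelling quality, as a covariate. The position of called genes was tested per chromosome and for the 25 genes on each side of Gimap5 with Fisher's exact test, two-sided. The Iddm regions named in the design were left out, since the sources used here give no coordinates for them.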

Results

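Gene expression was measured in isolated pancreatic islets of rats 40 days old, before insulitis appears in the diabetes-prone line. The BB (BioBreeding) rat is a model of autoimmune diabetes, and lyp is its lymphopenia locus, where a mutation of Gimap5, a GTPase needed for T cell survival, removes most T cells. The groups were DR+/+ and JB, which are BB-related and lack the mutation, JBlyp/lyp, which is BB-related and carries it, and F344 and F344lyp, control rats without and with lyp, with 2 arrays each. These backgrounds are taken from the labels, which do not state how JB relates to DR. The replicates of a group correlated at 0.981 to 0.997 across probe sets. Values are log2 RMA intensities, and differences are on the log2 scale with their standard error (SE).

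**Figure D1:**
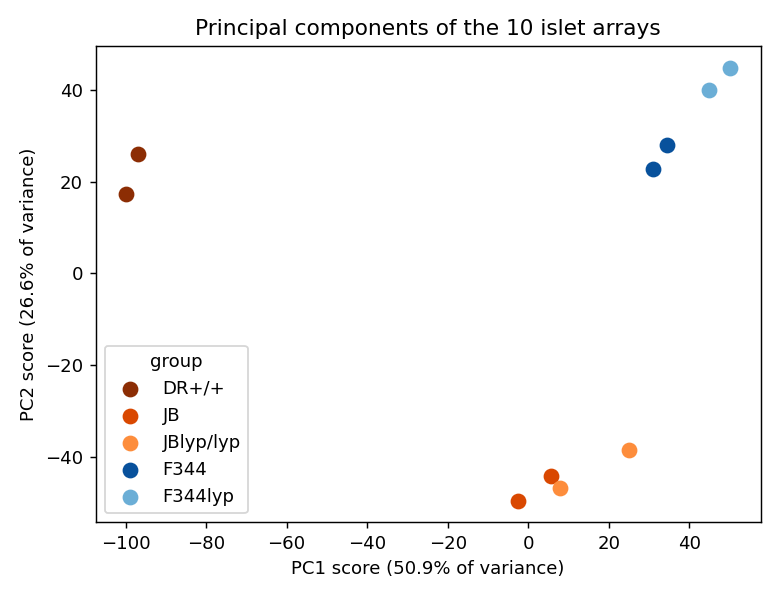
Principal components of the 10 arrays, with the first (50.9% of the variance) on the horizontal axis and the second (26.6%) on the vertical axis, 1 point per array coloured by group. The DR+/+ arrays lie at -96.8 and -99.9 on the first component, and the F344lyp arrays at 44.8 and 50.2.

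The comparison of the BB-related groups with the F344 groups addresses whether BB islets have a lower capacity to deal with oxidative stress. Antioxidant genes were lower in BB islets, pancreatic enzyme and regenerating genes were far lower, and immediate early genes were higher. The p-values of this comparison leave out the spread between groups of 1 side. With the strain as a random block, 63 of the named values called for it stayed past the threshold and 56 ended. The antioxidant genes that fell include Prdx4, a peroxiredoxin of the endoplasmic reticulum, by -1.91 (SE 0.18, adjusted p = 5.36e-05, limma with Benjamini-Hochberg, n = 6 BB and 4 F344 arrays), and Gpx4, which reduces lipid peroxides, by -1.10 (SE 0.22, adjusted p = 0.00375). The carrier gene Ucp2 fell by 1.25 and the glutathione peroxidase gene Gpx2 fell by 1.09. Of 48 antioxidant genes, 26 fell and 2 rose (27 and 2 when adjusted over the list alone), with a median difference of -0.39 (camera adjusted p = 0.000406, adjusted p = 0.305 with an estimated correlation). Glutathione transferases, which couple glutathione to toxic compounds, fell in 15 of 21 cases and rose in 0 (15 and 0 when adjusted over the list alone; camera adjusted p = 2.31e-05, adjusted p = 0.257 with an estimated correlation). Among them Mgst3 fell by 1.78, Gstm2 by -1.63, Gstm7 by -1.60 and Gstt1 by -1.13, and each was lower in all 6 BB arrays than in the 4 F344 arrays. The acinar marker list moved with these genes, at a median of -2.39.

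**Figure D2:**
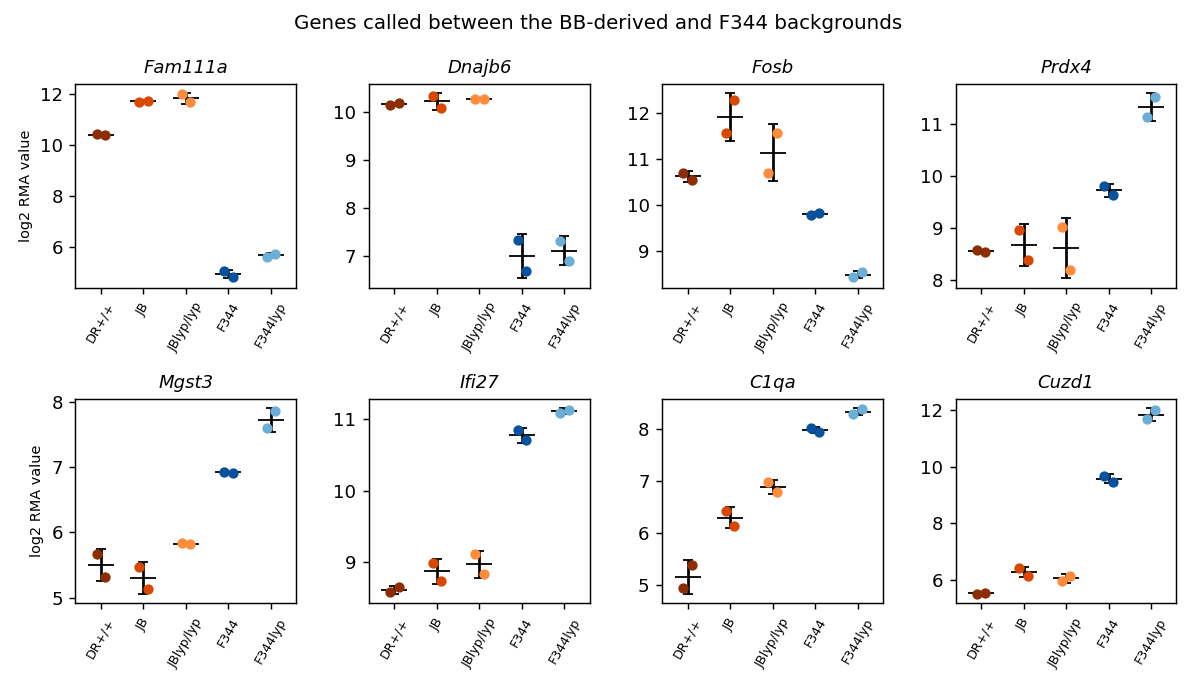
Log2 RMA values of 8 genes in the comparison of BB and F344 islets, 1 point per array, with the group mean and SD as bars (n = 2). Prdx4, Mgst3, Ifi27, C1qa and Cuzd1 are lower and Fam111a, Dnajb6 and Fosb are higher in the 6 BB arrays than in the 4 F344 arrays.

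The largest named fall was that of Prss3bl1, a serine protease gene of the trypsin family, at -5.94 (SE 0.19, adjusted p = 9.09e-08). Reg3a, a secreted lectin of the regenerating family, fell by 5.88 (SE 0.14, adjusted p = 1.46e-08), Reg3b by -4.42 and Reg1a by -4.18. Cuzd1, a zymogen granule protein of acinar cells, fell by 4.75, and the pancreatic protease inhibitor gene Serpini2 by -3.95. The named falls also hold Spink1l at -4.23, the pancreatic disulfide isomerase Pdia2 at -4.11, Cth, which makes cysteine for glutathione, at -3.83, Prss3 and Klk1b3 at -3.79 each, and the ribonuclease Ang at -3.75. Acinar genes fell in 32 of 34 cases and rose in 0 (32 and 0 when adjusted over the list alone; camera adjusted p = 1.55e-21, adjusted p = 0.115 with an estimated correlation). All 4 regenerating genes fell, with a median of -4.30 (4 when adjusted over the list alone; camera adjusted p = 5.88e-06, adjusted p = 0.144 with an estimated correlation).

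The largest named rise was that of Fam111a, a protease that acts at DNA replication forks, at 6.02 (SE 0.10, 64.8-fold, adjusted p = 1.9e-09), and all 6 BB arrays lay above the 4 F344 arrays. Ythdf2, a reader of methylated RNA, rose by 3.36 (SE 0.12), the co-chaperone gene Dnajb6 by 3.18 (SE 0.14) and the fatty acid hydroxylase gene Cyp4v3 by 2.94 (SE 0.14). RT1-T24-4 rose by 2.35, and other named rises of 2.14 to 2.28 were Tsc22d2, Tbc1d12, Itsn2, the endothelial transcription factor gene Sox17 and the matrix gene Thbs4. For rises of at least 4-fold, 5 of 43 other probe sets of the same genes showed at least 0.5 of the rise. RT1 genes, which encode the rat major histocompatibility complex, were called in 15 of 17 cases, against 37.9% of other genes (Fisher's exact test, p = 2.69e-05). The called probe sets of 10 went lower, those of 2 higher and those of RT1-Ba, RT1-Bb and RT1-CE5 both ways. Of RT1-Bb, a class II chain, 1 probe set rose by 2.26 and the other fell by 5.35, and of RT1-Ba 1 rose by 1.73 and another fell by 2.90, so no direction is given for these genes. The signal of RT1-Db1 fell by 1.96. A strain variant under the probes was not tested for falls. Lower RT1 signal, here and in the antigen presentation list below, thus need not be lower expression.

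Immediate early and stress genes, which respond within minutes to stimulation, rose in 20 of 33 cases and fell in 3 (20 and 3 when adjusted over the list alone; camera adjusted p = 4.65e-07, adjusted p = 0.103 with an estimated correlation). The transcription factor genes Fosb, Egr1 and Nr4a2 rose by 2.08, 1.36 and 1.33. Oxidative phosphorylation genes fell in 37 of 50 cases and rose in 1 (42 and 1 when adjusted over the list alone; camera adjusted p = 1.01e-08, adjusted p = 0.38 with an estimated correlation), among them the ATP synthase gene Atp5f1d at -1.79 and the complex I gene Ndufs3 at -1.37. Interferon response genes fell in 20 of 38 cases and rose in 4 (21 and 4 when adjusted over the list alone; camera adjusted p = 0.00381, adjusted p = 0.173 with an estimated correlation), with Ifi27 at -2.12 and the antiviral GTPase gene Mx1 at -1.46. Macrophage and dendritic cell markers fell in 24 of 44 cases and rose in 1 (25 and 1 when adjusted over the list alone; camera adjusted p = 3.71e-05, adjusted p = 0.14 with an estimated correlation), with the complement gene C1qa at -2.05 and the NADPH oxidase gene Cyba at -1.30. Antigen presentation genes fell in 19 of 28 cases and rose in 5 (19 and 5 when adjusted over the list alone; camera adjusted p = 0.0127, adjusted p = 0.408 with an estimated correlation), and RT1-Ba and RT1-Bb are among the 5. T cell markers fell in 13 of 33 cases and rose in 2 (17 and 2 when adjusted over the list alone; camera adjusted p = 0.0224, adjusted p = 0.26 with an estimated correlation). The 2 rises depended on which arrays were included. Without JBlyp/lyp replicate 1 the T cell call ended (camera adjusted p = 0.0606). Without F344 replicate 1 the T cell falls were 8. Antigen presentation falls were 12 without F344 replicate 1 or F344lyp replicate 2. The 3 immediate early falls were 1 without DR+/+ replicate 2 or any of the 4 F344 and F344lyp arrays.

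For some lists the result differed without the DR+/+ arrays, where camera p-values are adjusted within this comparison only. Beta cell genes fell in 22 of 37 cases and rose in 1 (22 and 1 when adjusted over the list alone; camera adjusted p = 0.000482, adjusted p = 0.305 with an estimated correlation), with the secretory granule gene Ptprn2 at -2.53. Without the DR+/+ arrays 8 fell and 11 rose (camera adjusted p = 0.209), and without F344 replicate 2 or F344lyp replicate 2 alone 14 fell. Endoplasmic reticulum stress genes fell in 15 of 28 cases and rose in 1 (17 and 1 when adjusted over the list alone; camera adjusted p = 0.00126, adjusted p = 0.362 with an estimated correlation), with Manf at -1.20. Without DR+/+ their median was -0.04 (camera adjusted p = 0.862). Endothelial markers rose in 17 of 33 cases and fell in 5 (18 and 7 when adjusted over the list alone; camera adjusted p = 0.00172, adjusted p = 0.242 with an estimated correlation), with the receptor gene Kdr at 1.07, and 9 fell without JBlyp/lyp replicate 1. Stellate and fibroblast markers rose in 20 of 49 cases and fell in 9 (22 and 10 when adjusted over the list alone; camera adjusted p = 0.0029, adjusted p = 0.372 with an estimated correlation), with the collagen crosslinking gene Lox at 1.44. Without DR+/+ the direction of the stellate list turned, with 5 higher, 16 lower and a median of -0.25 (camera adjusted p = 0.23), and the endothelial list had 5 higher, 8 lower and a median of 0 (camera adjusted p = 0.838). The antioxidant list had 21 falls and 1 rise without DR+/+ (camera adjusted p = 0.000193). The insulin genes were not called, with Ins1 at -0.09 (adjusted p = 0.389) and Ins2 at 0.04 (adjusted p = 0.758), nor was the pancreatic polypeptide gene Ppy at 0.07 (adjusted p = 0.816). The somatostatin gene Sst fell by 1.06, and the glucagon gene Gcg fell by 0.50 (adjusted p = 0.00727) but lay at 0.22 without DR+/+.

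The remaining fixed lists did not pass camera for BB against F344. The camera p-values below with DR+/+ or single arrays left out are adjusted within this comparison only. A pass there can come from that scale alone. Ductal markers fell in 12 of 25 cases and rose in 2 (adjusted p = 0.0511; 6.36e-05 without DR+/+). Cell cycle genes fell in 11 of 42 cases and rose in 3 (adjusted p = 0.0596; 0.00028 without DR+/+), hypoxia and glycolysis genes fell in 12 of 31 and rose in 1 (adjusted p = 0.0929), and chemokine genes fell in 11 of 52 and rose in 8 (adjusted p = 0.936). The ductal list passed without any array but DR+/+ replicate 1 and F344lyp replicate 2 (adjusted p = 0.0179 to 0.0472). The cell cycle list passed without DR+/+ replicate 1, JB replicate 2, JBlyp/lyp replicate 2, F344 replicate 2 or F344lyp replicate 1 (adjusted p = 0.0315 to 0.0446). Apoptosis genes had an adjusted p of 0.344, other endocrine markers of 0.747 (0.0465 without DR+/+), B cell markers of 0.628, mast and eosinophil markers of 0.327, erythroid markers of 0.217, nerve and Schwann markers of 0.68, and Gimap genes of 0.312. Of the added lists, intestinal epithelium markers fell in 19 of 28 cases and rose in 0 (camera adjusted p = 4.16e-06, adjusted p = 0.0903 with an estimated correlation), and mesothelial markers rose in 8 of 17 cases and fell in 1 (camera adjusted p = 0.000925, adjusted p = 0.0928 with an estimated correlation). Without DR+/+ the mesothelial call ended and its direction turned, with 1 higher, 5 lower, a median of -0.068 and a camera adjusted p of 0.577.

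Of the 14217 probe sets that represent a gene, as used in the lists, 1888 were called higher and 3501 lower in BB against F344. Falls thus outnumbered rises over all genes, and falls in a list are to be read against that. Over all probe sets, 10300 of 31042 were called, 5019 higher and 5281 lower, and 191 genes had probe sets called both ways. With 2 group means the count was 3518, with the strain as a random block 959, and without F344 replicate 1 it was 6742. The 3′ to 5′ Gapdh difference was 0.93 higher in BB than in F344 arrays, and with it as a covariate 8 probe sets were called.

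**Figure D3:**
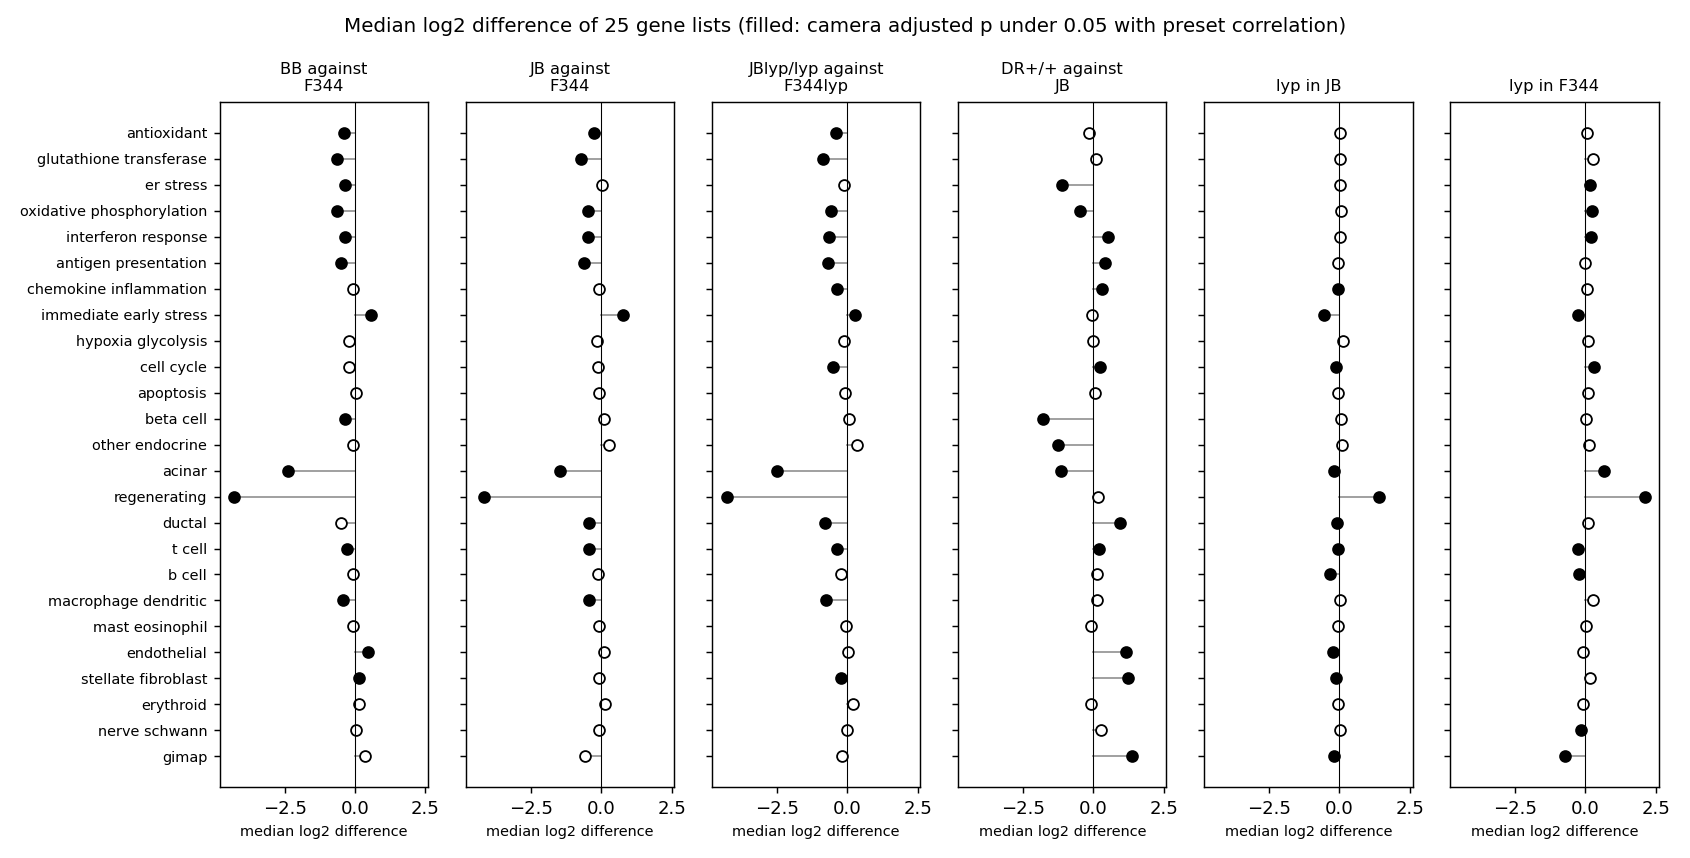
Median log2 difference of the 25 fixed gene lists (horizontal axis) in 6 comparisons, with a filled point where the camera adjusted p was under 0.05 at the preset correlation. The antioxidant list lies at -0.39 for BB against F344, -0.26 for JB against F344 and -0.41 for JBlyp/lyp against F344lyp.

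The background was also compared within each lyp genotype, JB against F344 without lyp and JBlyp/lyp against F344lyp with it, which share no array. Antioxidant genes were lower in BB islets in both: 10 of 48 fell and 0 rose without lyp (11 and 0 when adjusted over the list alone; camera adjusted p = 0.000723, adjusted p = 0.33 with an estimated correlation), and 12 fell and 1 rose with it (17 and 1 when adjusted over the list alone; camera adjusted p = 0.000887, adjusted p = 0.334 with an estimated correlation). Without lyp, the peroxiredoxin gene Prdx5 fell by 0.99, the mitochondrial carrier gene Ucp2 by -1.08 and Prdx4 by -1.05 (SE 0.27, adjusted p = 0.0356). With lyp, Prdx4 fell by 2.71 (SE 0.27, adjusted p = 0.000269), Gpx2 by -2.47, the quinone reductase gene Nqo1 by -1.16 and the haem oxygenase gene Hmox1 by -1.14. Glutathione transferases fell in 10 of 21 cases without lyp (13 when adjusted over the list alone; camera adjusted p = 4.77e-06, adjusted p = 0.234 with an estimated correlation) and in 13 with it (15 when adjusted over the list alone; camera adjusted p = 3.52e-07, adjusted p = 0.204 with an estimated correlation). The acinar list stood at a median of -1.47 without lyp (29 of 34 fell; camera adjusted p = 2.77e-19, adjusted p = 0.131 with an estimated correlation) and at -2.49 with it (32 fell; camera adjusted p = 4.27e-30, adjusted p = 0.103 with an estimated correlation). Without lyp, the falls without F344 replicate 1 were 2 antioxidant, 5 glutathione transferase and 14 acinar genes. Without F344 replicate 2 they were 3 antioxidant and 19 acinar genes. With lyp, the antioxidant falls were 20 without JBlyp/lyp replicate 1, 7 without JBlyp/lyp replicate 2 and 6 without F344lyp replicate 2, where the glutathione transferase falls were 7. These camera calls passed without each array.

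The immediate early list rose in both, with 16 of 33 genes higher and 0 lower without lyp (20 and 2 when adjusted over the list alone; camera adjusted p = 4.42e-10, adjusted p = 0.103 with an estimated correlation) and 11 higher and 3 lower with it (15 and 3 when adjusted over the list alone; camera adjusted p = 0.000159, adjusted p = 0.153 with an estimated correlation). Macrophage markers fell in 17 of 44 cases without lyp (23 when adjusted over the list alone; camera adjusted p = 9.74e-07, adjusted p = 0.103 with an estimated correlation) and in 24 with it (26 when adjusted over the list alone; camera adjusted p = 1.09e-08, adjusted p = 0.103 with an estimated correlation). Cell cycle genes fell in 18 of 42 cases with lyp (21 when adjusted over the list alone; camera adjusted p = 7.69e-07, adjusted p = 0.103 with an estimated correlation), and without it the list did not pass (adjusted p = 0.48). Without lyp, the macrophage falls were 3 and the immediate early rises 9 without F344 replicate 1, and 5 and 10 without F344 replicate 2. The macrophage falls were 8 without JB replicate 2. With lyp, the macrophage falls were 14 and the cell cycle falls 6 without F344lyp replicate 2. The cell cycle falls were 7 without F344lyp replicate 1 and 11 without JBlyp/lyp replicate 2. The 3 immediate early falls were 0 and 1 without F344lyp replicate 2 and JBlyp/lyp replicate 2. Fam111a rose by 6.78 without and 6.17 with lyp, Dnajb6 by 3.23 and 3.18, and Cyp4v3 by 3.45 and 3.17. Among the falls Reg3a stood at -5.43 and -5.36, and Prss3bl1 at -5.14 and -5.68. Of the 14217 probe sets that represent a gene, 681 were called higher and 1168 lower without lyp, and 668 higher and 1605 lower with it. Over all probe sets the counts were 3595 without lyp (1933 higher, 1662 lower) and 4383 with it (2040 higher, 2343 lower). The surplus of rises without lyp was thus not seen over genes. Of the called probe sets, 1136 were higher in both, against 127 from independent calls, 1029 were lower in both, against 125.4, and 5 and 2 went opposite ways. Without F344 replicate 1 the first count was 879, without F344 replicate 2 it was 1137 and without JB replicate 2 it was 2246, while the second was 1404 without F344lyp replicate 2, 2385 without F344lyp replicate 1 and 2896 without JBlyp/lyp replicate 2. With the Gapdh covariate 1 and 103 probe sets were called.

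The effect of lyp was compared in JB without pairing arrays. That JB and JBlyp/lyp share a background is read from their names. A difference of background thus cannot be told apart from lyp here, in the average or in the difference between the lyp effects. JBlyp/lyp was not compared with DR+/+. JB and JBlyp/lyp arrays of the same replicate number deviated from their group means together (correlation 0.652), and that spread stays in the error. A pairing of these arrays alone was not tested. In the unpaired test 1 of 31042 probe sets passed. It belongs to Reg3a, which rose by 2.55 (SE 0.22, 5.87-fold, adjusted p = 0.0177), from 4.63 ± 0.23 (SD, n = 2) in JB to 7.18 ± 0.38 in JBlyp/lyp arrays. Gimap5 was at 7.05 and 5.95 in the JB arrays and at 5.95 and 5.65 in the JBlyp/lyp arrays, a difference of -0.70 (SE 0.29, adjusted p = 0.785) that was not called. JB replicate 2, labelled as free of lyp, thus lay at the level of the lyp arrays for Gimap5, and also for Gimap7, at 3.73 against 3.60 and 3.67 in JBlyp/lyp. For the T cell gene Cd3d it lay with JB replicate 1, at 5.66 and 5.64 against 4.92 and 4.99. As a list, immediate early genes were lower in JBlyp/lyp, with a median of -0.54, where 0 of 33 passed (17 lower and 0 higher when adjusted over the list alone; camera adjusted p = 2.32e-25, adjusted p = 0.103 with an estimated correlation). B cell markers had a median of -0.35, where 0 of 15 passed (5 lower when adjusted over the list alone; camera adjusted p = 1.84e-08, adjusted p = 0.103 with an estimated correlation). T cell markers had a median of -0.05, where 0 of 33 passed (6 lower when adjusted over the list alone; camera adjusted p = 9.71e-05, adjusted p = 0.111 with an estimated correlation), and this call ended without JBlyp/lyp replicate 1 (adjusted p = 0.0563). Of endothelial markers 29 of 33 lay below 0 and 0 passed (camera adjusted p = 1.13e-05, adjusted p = 0.14 with an estimated correlation). Of acinar markers 27 of 34 lay below 0 (camera adjusted p = 0.000351, adjusted p = 0.432 with an estimated correlation), and of ductal markers 16 of 25 (camera adjusted p = 0.0126, adjusted p = 0.419 with an estimated correlation). Without JB replicate 1 these calls ended at adjusted p = 0.153 and 0.601, and without JBlyp/lyp replicate 2 at 0.956 and 0.578. The regenerating list had a median of 1.41 (3 higher and 1, Reg3g, lower when adjusted over the list alone; camera adjusted p = 0.000205, adjusted p = 0.209 with an estimated correlation). Camera also passed for the stellate (adjusted p = 0.00681, 0.408 with an estimated correlation), cell cycle (0.00739, 0.209), Gimap (0.0124, 0.154), chemokine (0.0451, 0.158) and added mesothelial lists (0.00452, 0.125), all below 0. Without JBlyp/lyp replicate 1 the cell cycle (adjusted p = 0.113), Gimap (0.0992), chemokine (0.113) and mesothelial (0.141) calls ended. Without JBlyp/lyp replicate 2 the stellate (0.596), cell cycle (0.0566), Gimap (0.115) and chemokine (0.226) calls ended. Without JB replicate 1 the stellate (0.0706) and Gimap (0.12) calls ended. The same held without JB replicate 2 for the cell cycle (0.238) and chemokine (0.323) calls, and without F344lyp replicate 1 or 2 for the chemokine call (0.0684). The 3′ to 5′ Gapdh difference of JBlyp/lyp minus JB was -0.65. With it as a covariate the mean of the T cell list went from -0.21 (SE 0.04) to -0.06 (SE 0.04), that of the B cell list from -0.40 (SE 0.04) to -0.43 (SE 0.08), and that of the immediate early list from -0.53 (SE 0.06) to -0.62 (SE 0.13). The mean of the Gimap list went from -0.31 (SE 0.11) to 0.01 (SE 0.19). The antioxidant list, at 0.04, did not pass (camera adjusted p = 0.793). At an unadjusted p under 0.05, 1935 probe sets passed. The limma count was 0 without DR+/+ replicate 1 or 2, JB replicate 1 or 2 or F344lyp replicate 1 or 2, and 4 without JBlyp/lyp replicate 2.

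**Figure D4:**
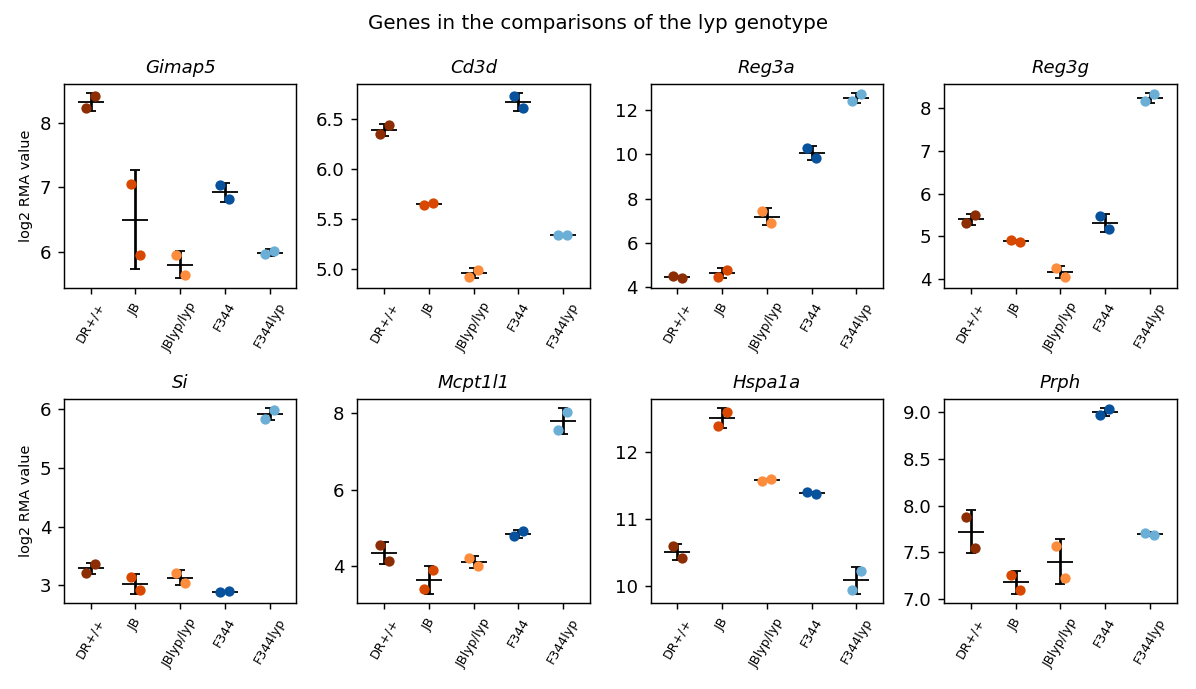
Log2 RMA values of 8 genes in the lyp comparisons, 1 point per array, with the group mean and SD as bars (n = 2). Reg3g, Si and Mcpt1l1 are higher in F344lyp than in F344 arrays and were not called in JBlyp/lyp against JB, while Cd3d and Hspa1a lie lower with lyp on both backgrounds.

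In F344 islets the comparison of lyp gave more calls than in JB. For gut, exocrine, regenerating and mast cell genes the makeup of the preparation cannot be told apart from lyp, here and in the average below. T cell genes were lower in F344lyp, with the T cell receptor complex gene Cd3d at -1.32 (SE 0.13, adjusted p = 0.000937), the coreceptor gene Cd8a at -1.14 and the transcription factor gene Tcf7 at -1.02. Regenerating genes were higher, with Reg3g at 2.92 (SE 0.16, adjusted p = 4.53e-05), Reg3a at 2.49, Reg1a at 1.75 and Reg3b at 1.06. The largest rise was that of Lypd8, an intestinal epithelial protein, at 3.38 (SE 0.17, adjusted p = 3.82e-05), and Si, the intestinal sucrase gene, rose by 3.03. Mast cell protease genes rose, with Mcpt1l1 at 2.94, Cma1 at 2.62 and Cpa3 at 2.13, as did the prostaglandin receptor gene Ptger3, the ribonuclease gene Ang at 2.83 and the acinar transcription factor gene Ptf1a at 2.51. Other named rises were the water channel gene Aqp8 at 2.68 and the creatine synthesis gene Gatm at 2.67. Named falls included Mga at -2.27, Scgb1c1 at -2.04, the neuropeptide gene Vip, and the intermediate filament gene Prph at -1.30. Gimap5 was at 7.03 and 6.82 in F344 and at 5.96 and 6.02 in F344lyp arrays, and this difference did not pass (SE 0.29, adjusted p = 0.158). Among antioxidant genes Prdx4 rose by 1.60 (adjusted p = 0.0225) and the cystine transporter gene Slc7a11 by 1.14.

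Acinar markers rose in 12 of 34 cases in F344lyp and fell in 0 (17 and 0 when adjusted over the list alone; camera adjusted p = 1.71e-17, adjusted p = 0.142 with an estimated correlation), with a median of 0.67. All 4 regenerating genes rose (4 when adjusted over the list alone; camera adjusted p = 3.79e-08, adjusted p = 0.103 with an estimated correlation). T cell markers fell in 3 of 33 cases and rose in 0 (9 and 0 when adjusted over the list alone; camera adjusted p = 4.17e-05, adjusted p = 0.103 with an estimated correlation). Of the 5 Gimap genes 0 passed, and 3 were lower when adjusted over the list alone (camera adjusted p = 0.000582, adjusted p = 0.103 with an estimated correlation). Immediate early genes fell in 2 of 33 cases and rose in 1 (8 and 2 when adjusted over the list alone; camera adjusted p = 1.34e-05, adjusted p = 0.119 with an estimated correlation), with the heat shock gene Hspa1a at -1.30. Cell cycle genes rose in 2 of 42 cases (11 when adjusted over the list alone; camera adjusted p = 1.34e-05, adjusted p = 0.103 with an estimated correlation). The added intestinal epithelium list rose in 10 of 28 cases (17 when adjusted over the list alone; camera adjusted p = 6.91e-13, adjusted p = 0.0828 with an estimated correlation). Antioxidant genes rose in 2 of 48 cases and fell in 1 (camera adjusted p = 0.564), and mast and eosinophil markers rose in 4 of 25 (camera adjusted p = 0.0998; 0.00433 without F344lyp replicate 2). Without F344 replicate 1, F344 replicate 2 or F344lyp replicate 2 the acinar rises were 6, and without F344lyp replicate 1 they were 7. Without any 1 of these 4 arrays the regenerating rises were 2, the T cell fall 1 and the antioxidant rises 0, and the cell cycle rises were 0 or 1. Without 1 of the F344 or F344lyp arrays, the median of the immediate early list ran from -0.324 to -0.241 and that of the T cell list from -0.216 to -0.195. In all, 468 probe sets were called, 349 higher and 119 lower. The count was 58 without F344 replicate 2, 78 without F344 replicate 1, 76 without F344lyp replicate 2, 241 without F344lyp replicate 1 and 823 without JBlyp/lyp replicate 1 or 2, and 123 with the Gapdh covariate. With only F344 and F344lyp in the model it was 3230, and with array weights 2160.

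Averaged over both backgrounds, lyp islets had higher Reg3a, by 2.52, and Reg1a, by 1.71, and lower T cell genes, with the CD3 chain genes Cd3e at -1.06 and Cd3d at -1.01 (SE 0.09, adjusted p = 0.00131) and Tcf7 at -0.97. The average of Mcpt1l1, at 1.70, combines 2.94 in F344 with 0.46 in JB (adjusted p = 0.825). Of stress genes, Hspa1a fell by 1.11 (SE 0.11, adjusted p = 0.0017) and the transcription factor gene Jun by -0.83. Immediate early genes fell in 7 of 33 cases and rose in 0 (18 and 1 when adjusted over the list alone; camera adjusted p = 1.12e-16, adjusted p = 0.103 with an estimated correlation). T cell markers fell in 4 of 33 cases (12 when adjusted over the list alone; camera adjusted p = 1.51e-06, adjusted p = 0.103 with an estimated correlation), and B cell markers in 1 of 15 (5 when adjusted over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.103 with an estimated correlation). All 4 regenerating genes rose in the average (4 when adjusted over the list alone; camera adjusted p = 1.24e-09, adjusted p = 0.103 with an estimated correlation), but Reg3g stood at 2.92 in F344 and at -0.73 in JB (adjusted p = 0.353). Acinar markers moved with them, with 6 of 34 higher and 0 lower (11 and 0 when adjusted over the list alone; camera adjusted p = 7.97e-08, adjusted p = 0.292 with an estimated correlation). So did the added intestinal epithelium list, with 8 of 28 higher and 0 lower (camera adjusted p = 1.11e-08, adjusted p = 0.0903 with an estimated correlation). Without F344 replicate 1, F344 replicate 2 or F344lyp replicate 2 the regenerating rises were 2, and the acinar rises were 3, 2 and 3. The immediate early falls were 3 without any of the DR+/+ and JB arrays, 1 without an F344 array and 2 without an F344lyp array. The T cell falls were 1 without an F344 array and 2 without DR+/+ replicate 1 or 2, JB replicate 1 or an F344lyp array. The B cell fall was 0 without any 1 of these arrays. Gimap5 stood at -0.82 (SE 0.21, adjusted p = 0.109) and was not called. In all, 243 probe sets were called, 155 higher and 88 lower. The count was 34 without F344 replicate 2, 38 without F344 replicate 1, 48 without F344lyp replicate 2, 122 without DR+/+ replicate 1 or 2, 128 without JB replicate 1, 135 without F344lyp replicate 1 and 424 without JBlyp/lyp replicate 2, and with the Gapdh covariate limma called 0, with 1334 at an unadjusted p under 0.05.

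The difference between the lyp effects in JB and F344 was tested directly. It was below 0 for gut and exocrine genes, led by Reg3g at -3.65, Lypd8 at -3.52 (SE 0.24, adjusted p = 0.000579), Si at -2.93, the amylase gene Amy1 at -2.80, Ptf1a at -2.79 and Tinag at -2.75. Acinar genes had a lower lyp effect in JB in 7 of 34 cases and a higher one in 0 (16 and 0 when adjusted over the list alone; camera adjusted p = 1.07e-24, adjusted p = 0.103 with an estimated correlation), and the 7 were 3 without F344 replicate 1 or F344lyp replicate 1 and 2 without F344 replicate 2 or F344lyp replicate 2. The cell cycle list passed as well, with 0 of 42 genes called (4 lower when adjusted over the list alone; camera adjusted p = 2.92e-08, adjusted p = 0.103 with an estimated correlation). The antioxidant list did not (camera adjusted p = 0.711), nor did the T cell list (camera adjusted p = 0.171). For gut and exocrine genes the makeup of the preparation cannot be told apart from lyp here either. In all, 88 probe sets were called, 9 higher and 79 lower. The count was 18 without F344 replicate 2, 19 without F344lyp replicate 2, 23 without F344 replicate 1, 37 without F344lyp replicate 1 and 54 without JB replicate 1, and 7 with the Gapdh covariate.

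DR+/+ and JB, the groups without lyp on a BB-related background, were compared with each other. Genes of secretory islet cells were lower in DR+/+ islets, and genes of mesothelium, connective tissue and vessels were higher. The prolactin receptor gene Prlr fell by 4.24, the prohormone convertase gene Pcsk2 by -3.06 (SE 0.17, adjusted p = 6.17e-06), and C2cd4b by -4.50. Hormone genes fell too, with Sst at -2.23, Ppy at -2.06, Gcg at -1.97 and Ins2 at -0.48 (adjusted p = 0.0182), and Ins1 at -0.33 was not called (adjusted p = 0.0674). The chloride exchanger gene Slc26a3 rose by 4.69 (SE 0.17, adjusted p = 2.75e-06), the mesothelial genes Upk1b by 4.21, Bnc1 by 4.20 and Wt1 by 3.58, the prostaglandin synthase gene Ptgs2 by 3.34, the complement gene C1s by 2.46 and the tight junction gene Cldn5 by 2.02. Gimap5 rose by 1.82 (SE 0.29, adjusted p = 0.00119), with 8.22 and 8.41 in the DR+/+ arrays.

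**Figure D5:**
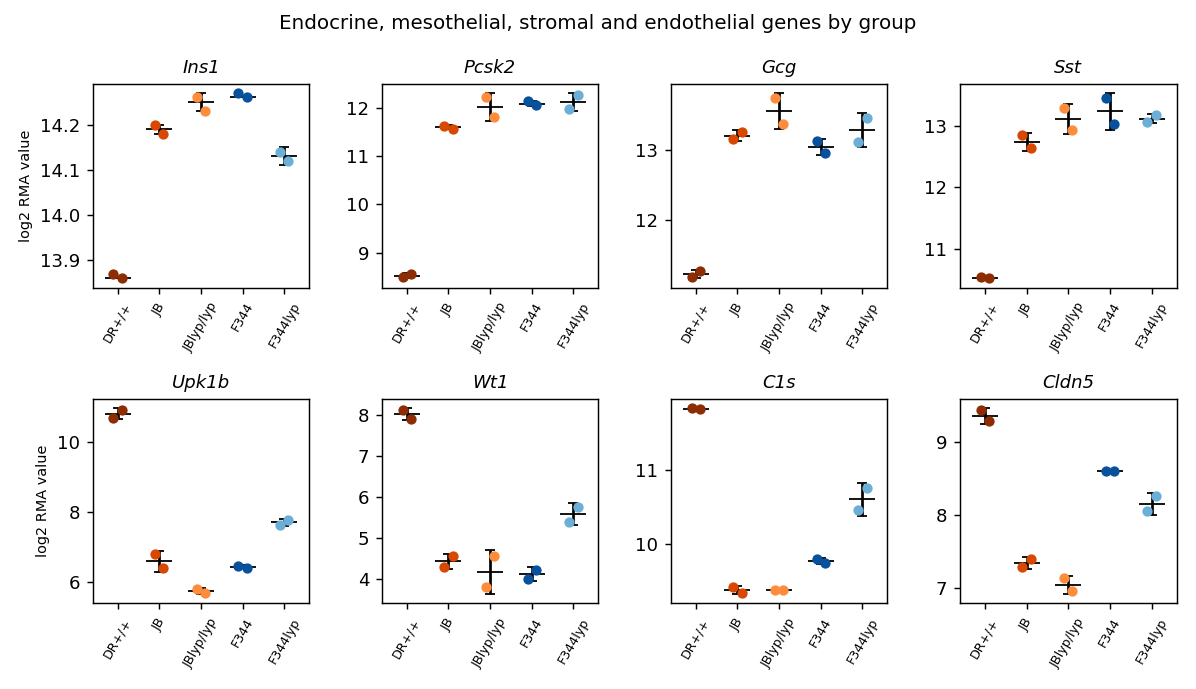
Log2 RMA values of 8 genes in the comparison of DR+/+ and JB, 1 point per array, with the group mean and SD as bars (n = 2). Pcsk2, Gcg and Sst are lower and Upk1b, Wt1, C1s and Cldn5 higher in DR+/+ than in JB arrays, while Ins1 differs by -0.33.

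Beta cell genes fell in 30 of 37 cases and rose in 1 in DR+/+ against JB (31 and 1 when adjusted over the list alone; camera adjusted p = 9.22e-14, adjusted p = 0.103 with an estimated correlation). Endoplasmic reticulum stress genes fell in 24 of 28 cases (camera adjusted p = 2.22e-09, adjusted p = 0.14 with an estimated correlation), among them the chaperone gene Hyou1 at -2.52 and Manf at -2.28. Acinar markers fell in 22 of 34 cases and rose in 4 (24 and 4 when adjusted over the list alone; camera adjusted p = 0.000101, adjusted p = 0.411 with an estimated correlation). Stellate and fibroblast markers rose in 32 of 49 cases and fell in 0 (39 and 0 when adjusted over the list alone; camera adjusted p = 7.67e-16, adjusted p = 0.103 with an estimated correlation). Endothelial markers rose in 23 of 33 cases and fell in 0 (26 and 0 when adjusted over the list alone; camera adjusted p = 6.82e-10, adjusted p = 0.103 with an estimated correlation). Gimap genes rose in 4 of 5 cases (camera adjusted p = 0.000966, adjusted p = 0.103 with an estimated correlation). T cell markers moved with them, with 8 of 33 higher and 0 lower (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0129, adjusted p = 0.237 with an estimated correlation). Without DR+/+ replicate 1, F344 replicate 1 or F344 replicate 2 these T cell rises were 5, and without DR+/+ replicate 2 they were 4. Interferon response genes rose in 18 of 38 and fell in 3 (22 and 4 when adjusted over the list alone; camera adjusted p = 9.71e-05, adjusted p = 0.103 with an estimated correlation). The chemokine gene Cxcl10 is among the falls, at -3.15. Antioxidant genes went both ways, with 9 higher and 10 lower of 48 (camera adjusted p = 0.552): Gpx8 rose by 2.08, Gpx3 fell by 2.02 and Sesn2 fell by 1.84. The added mesothelial list rose in 10 of 17 cases and fell in 1 (camera adjusted p = 1.14e-05, adjusted p = 0.0903 with an estimated correlation). In all, 8793 probe sets were called, 4028 higher and 4765 lower.

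The position of called genes was tested in place of the Iddm regions. Of the 51 genes around and including Gimap5, 0 were called for lyp in JB and 2, Gpnmb and Igf2bp3, for lyp in F344 (Fisher's exact test, two-sided, p = 0.254). For the difference between the lyp effects, a pair of chromosomes held more called genes than the others: 13 of 930 genes (1.4% against 0.416% elsewhere, Benjamini-Hochberg adjusted p = 0.00911) and 7 of 401 genes (1.75% against 0.443%, adjusted p = 0.0333). Fisher's test takes genes as independent. The genes called for this difference include gut and exocrine genes that moved together, so the excess does not point to a locus. No chromosome passed in the other 6 comparisons tested, and lyp in JB, with 1 call, was not tested this way.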

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

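The counts over splits of single arrays were planned before the data were examined, and the splits of whole groups and the tests of probe variants, RNA quality, islet share, added tissue and exocrine tissue were chosen after the results were seen.

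Probe sets that rose at least 4-fold in BB against F344, among them those of Ythdf2 and of Fam111a and Dnajb6, which have no other probe set, often rose without the other probe sets of their gene. Of 43 other probe sets of these genes with a mean at or above the median, 5 (11.6%) showed at least 0.5 of the rise, against 47 of 59 (79.7%) for rises between DR+/+ and JB (Fisher's exact test, two-sided, p = 4.15e-12, with probe sets of a gene not independent). With 1 probe set per gene the shares were 0 of 5 and 11 of 18 (Fisher's exact test, p = 0.0373), and the test was widened to all probe sets after that outcome was seen. RNA or labelling quality that follows the 3′ to 5′ Gapdh difference, as the sole cause, is argued against by a median of -0.22 for JBlyp/lyp minus JB over these 91 probe sets (quartiles -0.49 to 0.06), where that difference predicts -1.61. Their mean rise of 2.63 (SE 0.06) stood at 2.37 (SE 0.22), 2.76 (SE 0.34), 2.77 (SE 0.18) and 2.87 (SE 0.27) with the Gapdh difference and the poly-A, hybridisation and bioC controls as covariates. The slopes of these covariates come only from differences between the 2 arrays of a group, so quality that follows the groups in another way was not tested. A strain variant under the probes is therefore a candidate explanation for part of the rises, while transcripts that differ between the strains and a difference in regulation stay open and were not tested.

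The DR+/+ arrays stood apart from JB, with lower secretory genes and higher mesothelial, stellate and endothelial markers. A lower share of islet cells alone would raise other cell types alike, but the acinar change lay below the stellate and fibroblast change by -1.98 (SE 0.11). RNA quality was tested with covariates whose slopes come only from differences between the 2 arrays of a group. The actin 3′ to 5′ difference lay -1.07 and the poly-A controls 1.04 from JB. With each as a covariate the stellate and fibroblast difference of 1.11 (SE 0.08) stood at 1.24 (SE 0.17) and 1.11 (SE 0.27), and at 0.99 (SE 0.08) and 1.02 (SE 0.07) with the hybridisation and bioC controls. These tests replaced the Gapdh covariate after it had given 1.09 (SE 0.10), since Gapdh differed by only -0.22. Quality with such slopes does not account for the difference, but quality or a batch that follows the groups cannot be told apart from them. Added mesothelial and connective tissue that dilutes the rest alike would lower acinar and beta cell markers alike, but these changes differed by 0.76 (SE 0.13). Beta cell genes themselves fell by unlike amounts, Prlr and Pcsk2 far more than Ins1 and Ins2, so this gap does not decide against dilution. A change in the makeup of the preparation, a difference between the strains or both may remain. The design, with 2 arrays per group, holds no test that separates them.

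Antioxidant genes were lower in BB than in F344 islets, as was exocrine signal. Within groups the antioxidant mean followed the acinar mean with a slope of 0.43 (SE 0.04), and the acinar difference of -2.30 then predicts -0.99 (SE 0.09), a larger fall than the observed -0.43 (SE 0.05). Exocrine tissue in the preparation therefore cannot be told apart from a strain difference, since exocrine signal follows the background in this design; the requirement that prediction and observation match was added after the values were seen, and without it the slope would have counted for exocrine tissue. Between groups the relation was weaker, since F344lyp lay above F344 by 0.99 in acinar and 0.11 in antioxidant genes, and DR+/+ below JB by -0.87 and -0.11. RNA quality stays open as well: JBlyp/lyp minus JB was 0.02 (SE 0.08) where the Gapdh difference predicts 0.30, a gap of -0.28 (SE 0.12) not set apart from 0 once the error of the prediction was included, a step added after the values were seen and without which it would have counted against RNA quality, and BB minus F344 was -0.41 (SE 0.24) with the Gapdh, -0.37 (SE 0.32) with the poly-A, -0.49 (SE 0.08) with the actin, -0.73 (SE 0.09) with the hybridisation control and -0.89 (SE 0.14) with the bioC covariate.

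For BB against F344, 1 of 100 splits of the 10 arrays into 6 and 4, the real one, gave as many calls. In a model with 2 group means the real split gave 3518 calls and the highest other 115. Splits of single arrays mostly part the 2 arrays of a group, which resemble each other, and this alone lowers their counts. They therefore do not exclude chance. Arrays of a group share a strain, and the 10 splits that keep groups whole are too few for a share under 0.05: the real one gave 3518 and the highest other, DR+/+ with F344 and F344lyp against JB and JBlyp/lyp, gave 1803. For lyp averaged over both backgrounds the 18 splits are too few for a share under 0.05: 2 gave as many calls, with 19 for the real split of 8 arrays and 848 for the highest other. That other split sets replicate 1 of JB and JBlyp/lyp with F344lyp against replicate 2 with F344, which points to a structure of the samples, and replicate 1 arrays of JB and JBlyp/lyp correlated at 0.991, as did the replicate 2 arrays at 0.992, above the replicates of JB at 0.985.

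The effect of lyp differed between JB and F344 by the test of the difference itself for 88 probe sets, where the makeup of the preparation was not told apart from lyp. Prph stood above 0 at 1.52. Below 0 stood Muc1 at -1.92, Slc39a8 at -2.04, Lrrn4 at -2.06, Cpa3 at -2.08, Upk1b at -2.11, Lgals4 at -2.32, Clca1 at -2.36, Cma1 at -2.40, Mcpt1l1 at -2.49, Cuzd1 at -2.50 and Tmed6 at -2.59. Further below stood Aqp8 at -2.66, Tinag at -2.75, Ptf1a at -2.79, Amy1 at -2.80, Si at -2.93, Lypd8 at -3.52 and Reg3g at -3.65.

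The mean of the mast and eosinophil list in DR+/+ replicate 1, at 4.02, lay slightly above the other 5 BB arrays, which ran from 3.96 to 3.98. The gap was 0.627 of the range of all 6 BB arrays. It was 1 of 126 such checks, of which chance gives about 1 in 20, so this is no more than chance gives.

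Control probe sets, which the comparisons do not use, differed between groups. The labels give no hybridisation or scan date, and a batch that follows the groups cannot be told apart from them in any of the 8 comparisons. The mean of the hybridisation controls was 10.33 (SD 0.07) in DR+/+, 9.82 in JB, 9.06 in JBlyp/lyp, 8.87 in F344 and 8.46 in F344lyp arrays. The mean of the poly-A controls was 9.33 (SD 0.09) in DR+/+, 8.29 in JB, 7.40 in JBlyp/lyp, 7.47 in F344 and 6.64 in F344lyp arrays. The mean of the bioC controls, part of the hybridisation controls, was 9.45 in DR+/+, 9.05 in JB, 8.17 in JBlyp/lyp, 7.97 in F344 and 6.22 in F344lyp arrays.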

How the results depend on the processing

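The Gapdh covariate and the list tests without DR+/+ were chosen after the data were seen, and the other alternatives were planned. Equal array medians and quantile normalization kept each of the 8 counts within 1.5 times. Without each array in turn, the called probe sets numbered 6742 (without F344 replicate 1) to 11310 for BB against F344, 0 to 4 for lyp in JB, 58 to 823 for lyp in F344, 34 to 424 for lyp averaged, 18 to 130 for the difference between the lyp effects, 6148 to 9903 for DR+/+ against JB, 879 to 4751 for JB against F344 and 1404 to 5482 for JBlyp/lyp against F344lyp. Where that leaves a group with 1 array, the array is assumed to vary like the other groups. With 1 probe set per gene fewer probe sets are tested, and the counts were 5483 for BB against F344, 296 for lyp in F344, 4996 for DR+/+ against JB, 1891 for JB against F344 and 2313 for JBlyp/lyp against F344lyp. With a fold of at least 1.5 as well, BB against F344 gave 5188. The filter on dim probe sets gave 265 for lyp in F344, 130 for lyp averaged and 50 for the difference between the lyp effects, so part of these calls lay in dim probe sets, where signal over background limits the comparison. For BB against F344, 2 group means gave 3518 and the strain as a random block 959 (correlation 0.491), since spread between groups of a side then enters the error. Array weights gave 2160 for lyp in F344 and 0 for lyp in JB (limma, 1021 at an unadjusted p under 0.05). The trend gave 3 for lyp in JB. With only the groups compared the counts were 3230 for lyp in F344, 122 for lyp averaged, 1936 for JBlyp/lyp against F344lyp and 0 for lyp in JB (limma, 955 at an unadjusted p under 0.05); the cause was not tested. The replicate block gave 5 for lyp in JB, 745 for lyp in F344 and 486 for lyp averaged, but the labels give the numbers no shared animal, litter or day. Correlations of the replicate deviations were 0.652 for JB and JBlyp/lyp, a hint from the data that these arrays deviate together, and -0.101 to 0.237 for the other pairs of groups.

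With the Gapdh covariate the counts were 8 for BB against F344, 0 for lyp in JB (limma, 670 at an unadjusted p under 0.05), 123 for lyp in F344, 0 for lyp averaged (limma, 1334), 7 for the difference between the lyp effects, 6103 for DR+/+ against JB, 1 for JB against F344 and 103 for JBlyp/lyp against F344lyp. The calls ended mainly because the error grew: over the calls for BB against F344 the median size went from 0.59 (SE 0.12) to 0.60 (SE 0.49), with 88.7% on the same side of 0, and for JB against F344 from 0.90 (SE 0.18) to 0.85 (SE 0.59). For lyp in JB the size fell too, from 2.55 (SE 0.22) to 1.96 (SE 0.43). Of 547 values of named genes that were called, the covariate left 155 past the threshold, ended 382 and turned 10. It turned Alas2 to -0.11, Il2rg to 0.059 and Col6a2 to 0.64 for BB against F344, and Cdkn1a to -0.061, Ptprn to 0.62, Sod3 to 0.50, Mcpt1l1 to 0.33, Il2rg to 0.047, Ramp2 to 0.084 and Col6a2 to 0.70 for JB against F344. Without the DR+/+ group, BB against F344 turned to -0.53 for Bnc1, -0.28 for Efemp1, -0.034 for Gimap6, -0.31 for Gimap1, -0.11 for Fcer2 and 0.22 for Gcg. The sign for these genes thus rested on the DR+/+ arrays, and why DR+/+ differs was not tested. With the mean of a gene's probe sets in place of the brightest, the camera adjusted p passed for cell cycle in BB against F344 (0.0445), for glutathione transferase (0.0425), macrophage (0.0492), endothelial (0.047) and stellate (0.0261) lists in lyp in F344, and for interferon in lyp averaged (0.0485), and no longer passed for mesothelial in lyp in F344 (0.0692), cell cycle in lyp averaged (0.0501) and ductal in the difference between the lyp effects (0.051). Quantile normalization ended 15 of the 547 values and equal array medians 0. Of the named values called for BB against F344, the strain as a random block kept 63 and ended 56. With 2 group means 84 were kept and 35 ended.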

Other observations

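The probe sets of Wtap, Dhx36 and Sry were chosen after their values were seen, and the other values come from comparisons and lists that were planned.

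Several endocrine and stress genes of the DR+/+ arrays have not been described above. Against JB, the secretory granule genes Resp18 and Pcsk1n fell by 3.55 and 3.41, and Disp2 fell by 3.53. The monocarboxylate carrier gene Slc16a1, which beta cells normally keep low, rose by 3.82, the epithelial gene Scel by 3.71, the scavenger receptor gene Olr1 by 3.59 and the chloride channel gene Cftr by 2.34. The acinar enzyme gene Prss2 fell by 2.27. Ductal markers rose in 13 of 25 cases and fell in 2 (camera adjusted p = 0.000723, adjusted p = 0.311 with an estimated correlation; 4 fell without JBlyp/lyp replicate 1 or 2), and chemokine genes rose in 18 of 52 and fell in 1 (camera adjusted p = 0.000944, adjusted p = 0.103 with an estimated correlation; 11 rose without DR+/+ replicate 2).

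Further genes were called between BB and F344. The angiopoietin receptor gene Tek rose by 1.16 and the neutrophil attractant gene Cxcl1 by 1.40, while the complement gene C1qc fell by 2.27 and the mannose receptor gene Mrc1 by -1.25. The cofactor gene Sdf2l1 of the endoplasmic reticulum fell by 1.40 and the peptide gene Npy fell by 1.64.

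Probe sets of some genes gave different values. For Wtap, 1 probe set rose by 4.14 in BB against F344 and the other differed by 0. For Dhx36 the 5 probe sets ran from -0.08 to 3.69.

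The protocol names male animals, which the arrays do not settle. The 4 probe sets of Xist lay between 7.68 and 12.16 over the 10 arrays, that of Eif2s3y between 2.34 and 2.56, that of Sry between 2.97 and 3.46, and the Uty probe sets between 8.37 and 9.13 for 1 and at 3.45 to 3.99 on 9 arrays and 4 on JB replicate 1 for the other. Xist is transcribed in cells with a silenced X chromosome and the other genes lie on the Y chromosome, so these values leave open whether the probe sets measure their genes poorly or the animals were not male.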
